A study of Mus musculus with 8 samples.

How the data were processed

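RNA from mouse trigeminal ganglia was hybridised to 8 Affymetrix Mouse Genome 430 2.0 arrays, 4 from control mice and 4 from mice transgenic for daDREAM. The titles of all 4 transgenic samples carry the tag tg16. Per the labels' protocols, the animals were adult males of a C57B/6XCBA background handled in the light phase, cDNA was made from 4 µg of total RNA with a one-cycle labelling kit, and 15 µg of biotinylated cRNA was fragmented for hybridisation. The labels name the arrays of a group as biological replicates; whether an array holds ganglia of 1 animal or a pool is not given in the sources used here, so p-values measure the spread between these samples.

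The deposited values are log2 expression values per probe set, which the authors made with RMA in the affy package, per the submitters' processing notes. RMA subtracts background, quantile-normalizes the probes over all arrays and summarises each probe set by median polish. The package version and the probe set definitions are not given in the sources used here. The values carry 2 decimals and run from 3.39 to 14.94, with array medians from 7.09 to 7.13. Quantile normalization removes any shift shared by most genes, so differences are relative to the average gene. No 2 arrays held identical values, and correlations between arrays lay between 0.983 and 0.996.

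Of 45101 probe sets, 64 were Affymetrix controls and were left out of the tests. Platform annotation gave 34945 probe sets a single gene symbol, 932 several and 9160 none. A gene was represented by its single-symbol probe set with the highest mean over the 8 arrays, which left 18193 genes, 9010 of them with more than 1 probe set. Gene identifiers of 34741 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which was used only for the order of 18028 genes along chromosomes. No build is named for the arrays, so coordinates are not printed. Under the symbol Calca, the gene of the peptide CGRP, no single-symbol probe set was found, and it is not reported here.

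Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited log2 values, with group as the only term and Benjamini-Hochberg adjustment over genes. A gene or probe set passed the test at an adjusted p under 0.05. Gene lists, 34 in number with 663 measured memberships, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists. Beside each list stands the number of members that passed after adjustment over all genes and the number that passed when adjusted over the list alone. Single quantities were compared by a two-sided exact permutation test over the 70 assignments of 8 arrays to 2 groups of 4, whose smallest possible p is 0.0286. Neighbouring genes among the 100 genes with the smallest p were counted against 10000 random draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision.

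The gene test was tested on simulated data for the comparison of transgenic with control arrays over 18193 genes. The noise was normal and independent, with the same SD per gene in both groups, taken from the limma fit. It recovered 86.6% of genes changed by 0.5 log2, 100% of those changed by 1 and 100% of those changed by 2, and 3.5% of its calls were false. Over all changed genes in the simulation limma recovered 95.5% and an unequal-variance test per gene 61%. Equal spread in both groups is limma's own assumption and favours it. The simulation therefore cannot show how far lower power accounts for fewer calls by the latter test in the data.

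The test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are Kcnip3, the 12 genes with the largest positive and the 12 with the largest negative difference among genes that passed with non-overlapping groups (predicted or unnamed genes passed over), in each list up to 4 members that passed over the list alone or otherwise the 1 or 2 with the smallest p, and Pdyn, Bdnf, Penk, Fos, Calca, Tac1, Trpv1, Trpa1, Scn10a, Ptgs2 and Ptgds. Other genes named to complete a short count were chosen after their values were seen. Alternatives covered the replicate number as a block, renewed quantile normalization, median centring, filters on dim probe sets, other ways of choosing a gene's probe set, another variance prior, an unequal-variance test per gene, array weights, other thresholds and leaving out each array. Leaving out arrays with female, 18S, Gh or Acta1 signal, asking for agreement of a second probe set, leaving out neighbours of 1 gene family, and counting genes in fixed 10 Mb bins were chosen after seeing the data.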

Results

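The series asked how a transgene for DREAM alters gene expression in the trigeminal ganglion, which holds the cell bodies of the sensory neurons of the face. DREAM, the product of Kcnip3, is a calcium-binding protein that represses transcription and also binds Kv4 potassium channels, and daDREAM is a mutant form designed to stay active. RMA log2 expression values were compared between 4 control arrays and 4 arrays of daDREAM transgenic mice. All values below are means ± SD of n = 4 arrays per group, and differences are transgenic minus control.

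Kcnip3 itself showed no difference that passed the test. Its brighter probe set read 10.23 ± 0.15 in control and 10.26 ± 0.07 in transgenic ganglia, a difference of 0.03 (SE 0.08, limma adjusted p = 0.880). The other read 8.89 ± 0.32 and 9.17 ± 0.18 (difference 0.27, adjusted p = 0.346 over probe sets). Whether either probe set covers the transgene's transcript is not given in the sources used here, so these values do not check the labels. The sign of the 0.03 difference turned with several settings, for example to -0.04 after renewed quantile normalization.

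Single genes differed by large factors between the groups. Plppr1, a neuronal membrane protein of the lipid phosphatase family, was 6.96-fold higher in transgenic ganglia, and Rpgrip1, a protein of the photoreceptor cilium, was 24.7-fold lower. Also higher were Erdr1 by 5.31-fold, the ceramidase Acer3 by 4.07-fold, the unconventional myosin Myo7a by 3.57-fold and the synaptic vesicle protein Sv2c by 3.23-fold. Also lower were Ahnak2 by 10.1-fold, the lysosomal enzyme Galc by 8.06-fold, the ribonuclease angiogenin (Ang) by 6.05-fold, the zinc finger gene Zfp874a by 5.29-fold and Qrich1 by 5.22-fold.

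Transgenic means of Ang (4.85), Cldn34c1 (5.30), Zfp874a (5.42), Taf15 (5.73) and Galc (5.87) and control means of Serpina1c (5.28) and Serpina1b (5.55) lay below a log2 signal of 6, near background, so the differences of these genes are lower bounds at best. In full, Plppr1 read 6.06 ± 0.20 in control and 8.86 ± 0.07 in transgenic ganglia (difference 2.80, SE 0.10, limma adjusted p = 4.79e-08). Rpgrip1 fell from 10.71 ± 0.12 to 6.08 ± 0.32 (SE 0.14, adjusted p = 1.21e-08), and Ahnak2 from 12.50 ± 0.05 to 9.16 ± 0.18 (SE 0.09, adjusted p = 6.96e-09). The remaining named genes with higher values were Fam168a (1.66), Serpina1b (1.55), Pcyox1l (1.55), Trim34a (1.52), the retinoid carrier Rlbp1 (1.5), the calcium/calmodulin-dependent kinase Camk4 (1.44) and Serpina1c (1.44), as log2 differences. The remaining ones with lower values were the claudin gene Cldn34c1 (-2.02), the RNA-binding protein Taf15 (-1.84), the microtubule-binding protein Clasp2 (-1.59), Ly86 (-1.54), the phosphatase Ptp4a2 (-1.49) and the interferon-induced GTPase Iigp1 (-1.39). Serpina1b and Serpina1c belong to a family of near-identical copies, so their signals cannot be assigned to 1 copy with certainty.

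Different probe sets of a gene did not always move together. For Clasp2, 2 further probe sets fell (-1.98 and -1.48), and for Plppr1 another rose by 1.85. For Rpgrip1 the next brightest probe set differed by 0.07 and for Taf15 by 0.03. For Fam168a a probe set of similar brightness read -0.065, while others rose by 1.325 and 0.94. For Ptp4a2 the next brightest read 0.315, against -1.49 at the probe set that represents it. The other Acer3 probe sets read 0.22, 0.16 and 0.62, against 2.025. Galc had another probe set that was higher, by 0.48 (adjusted p = 0.00434 over probe sets), and in Camk4 another was lower, at -0.48 (adjusted p = 0.00545). For Gfap, the intermediate filament of astrocytes, the brightest probe set differed by 1.59 without passing (adjusted p = 0.0660 over genes). The next brightest read 0.65 (adjusted p = 0.307 over probe sets), while the dimmest rose by 3.15 (adjusted p = 6.22e-09 over probe sets). The control mean of the dimmest was 5.86, below a log2 signal of 6 and near background.

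Across the genome, 364 of 18193 genes passed the limma test, 179 higher and 185 lower in transgenic ganglia. Groups did not overlap in 363 of them, and 59 changed at least 2-fold. Over all genes, 1953 (10.73%) had groups that did not overlap, where chance gives 2.86%, and 3307 (18.18%) had an unadjusted p under 0.05. Of 45037 probe sets, 1236 passed, 640 higher and 596 lower, and 274 of these lacked a single gene symbol. The gene count came to 229 without transgenic replicate 2 and 236 without transgenic replicate 3. It came to 49 with an unequal-variance test per gene, and to 98 without control replicate 3 and transgenic replicates 3 and 4, the arrays with the most Gh.

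**Figure D1:**
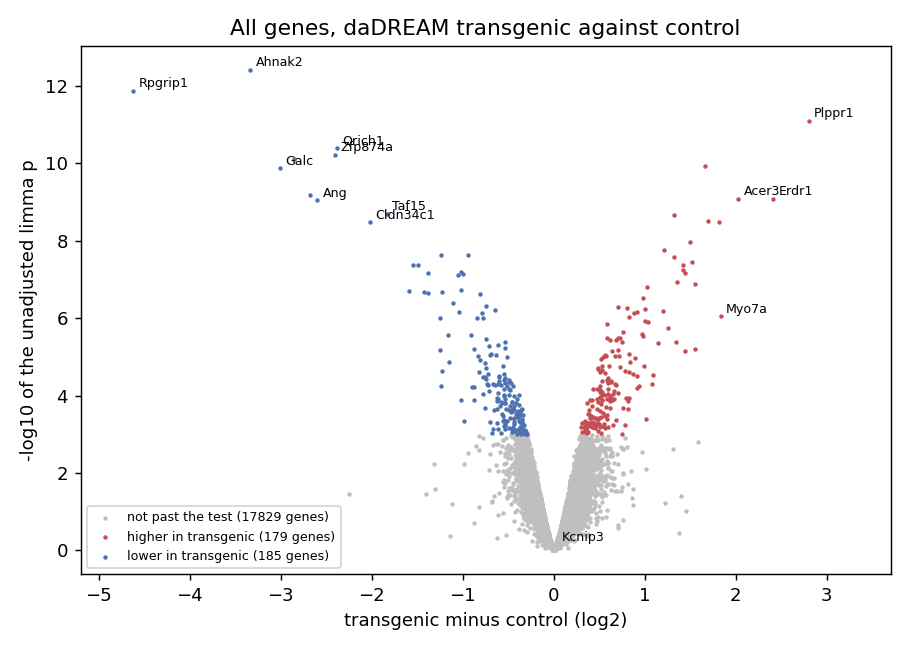
Transgenic minus control log2 difference (horizontal) against -log10 of the unadjusted limma p (vertical) for 18193 genes; red and blue points mark genes that passed the test, 179 higher and 185 lower. Rpgrip1 and Ahnak2 lie farthest to the left with Galc, Plppr1 farthest to the right, and Kcnip3 near 0.

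**Figure D2:**
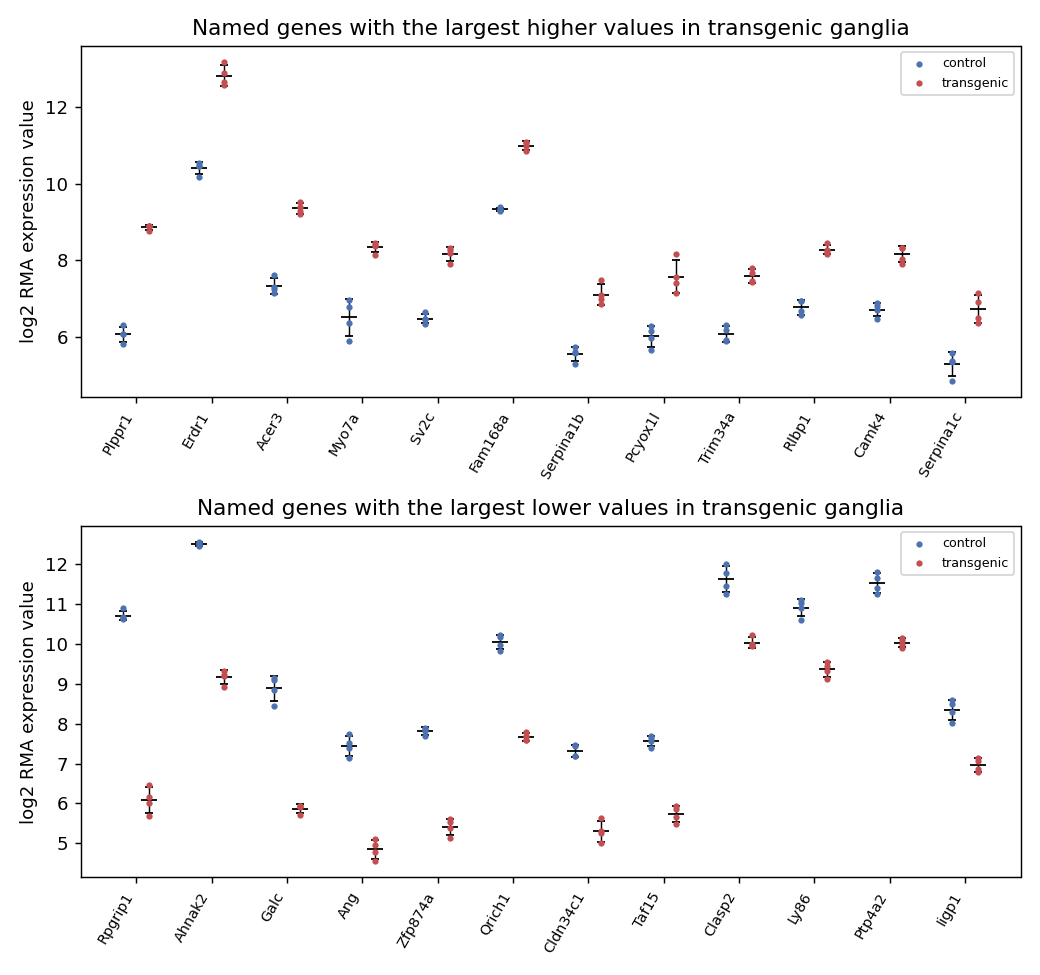
Log2 RMA expression values per array for the 12 named genes with the largest higher values (top) and the 12 with the largest lower values (bottom) in transgenic ganglia; points are arrays (blue control, red transgenic), dashes are means and bars are SDs of n = 4. No control array overlaps the transgenic arrays in any of these genes.

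Interferon response genes were lower in transgenic ganglia. Of 17 measured members, 6 fell: Iigp1, Oasl2, Usp18, Ifit1, Gbp2 and Ifit3, the last pair named after their values were seen. Usp18, which removes the ubiquitin-like ISG15, fell 2.24-fold, the RNA sensor effector Ifit1 2.23-fold and the antiviral gene Oasl2 1.67-fold. For Iigp1 the other probe set read -0.56 on the log2 scale without passing (limma adjusted p = 0.149 over probe sets). Adjusted over the list alone, 12 members were lower and 0 higher, with limma. The list's median difference was -0.38, and camera gave an adjusted p of 3.14e-11. The estimated inter-gene correlation gave an adjusted p = 0.0996 for this list, and none of the 34 lists passed with it. Without the arrays with the most Gh, 3 members passed over all genes and 9 over the list alone, all lower. There camera's adjusted p at the preset correlation was 1.92e-07.

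Circadian clock genes moved in both directions. Dbp, an output gene of the clock, fell 2.34-fold (10.37 ± 0.40 to 9.14 ± 0.23, limma adjusted p = 0.00370), and Per2, Per1 and Ciart fell by 0.76, 0.62 and 0.54 on the log2 scale. Arntl, the activator that drives them, rose by 0.80 (adjusted p = 0.0113) at its brighter probe set, while the other read -0.20. For Per2 the other 2 probe sets read -0.40 and 0.07. Thus 1 of 17 members rose, 4 fell and 12 did not pass; adjusted over the list alone, 2 were higher and 7 lower. The 5 members past the test fell to 2 without control replicate 4 or without transgenic replicate 1, 2 or 3, and to 3 without control replicate 3. The list passed camera as lower (adjusted p = 0.0231; adjusted p = 0.734 with an estimated correlation, and 0.111 by ranks, where it does not pass). Without control replicates 3 and 4 and transgenic replicate 4, the arrays with female signal, Dbp, Per2 and Arntl passed and camera's adjusted p was 0.214. Leaving out control replicate 3 alone gave an adjusted p of 0.151. Without the arrays with the most Gh 1 clock gene passed, as lower, and camera's adjusted p was 0.109. Per1 was named after its value was seen.

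Of receptors for the transmitters glutamate and GABA, 3 of 26 were higher. Gabra2 rose 1.96-fold, Gabrb1 1.57-fold and Gabrb2 1.38-fold, all subunits of the inhibitory GABA-A receptor, and the other 23 members did not pass. Other Gabrb1 probe sets read 0.41, -0.18 and -0.015 on the log2 scale, and none passed over probe sets. Other Gabrb2 probe sets read 0.49, 0.335, 0.11 and 0.07, and none passed. For Gabra2 another probe set rose by 1.14 (limma adjusted p = 3.01e-05 over probe sets). Its remaining ones read 0.765, 0.37 and 0.20 without passing. Adjusted over the list alone, 3 receptors were higher and 0 lower, and the list passed camera as higher (adjusted p = 0.00852; adjusted p = 0.734 with an estimated correlation). Without control replicates 1 and 4, which had the most 18S signal, camera's adjusted p was 0.0695. The 3 receptors past the test became 1 without control replicate 1, 2 or 4 or transgenic replicate 2 or 3. They became 0 without the arrays with the most Gh, where camera's adjusted p was 2.16e-04. Over the list alone 10 passed without transgenic replicate 4 and 5 without control replicate 3. Gabrb1 was lowest on control replicate 4 (8.24) and highest on transgenic replicate 3 (9.43), as was the central nervous system marker Gfap (8.29 and 11.24). Of 17 such markers 16 values were above 0 and 1 passed. Gabra2 is also on the list of genes known to vary between inbred strains, of whose 6 members it alone passed. On that list 2 members were higher and 1 lower when adjusted over the list alone, with Wdfy1 at 0.76 and H2-Ea at -0.36, and camera's adjusted p was 0.951.

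Of granulocyte and marrow markers, 3 of 14 were higher. S100a8 and S100a9, the subunits of calprotectin, rose 2.04-fold and 2.11-fold, and Lcn2, the iron-carrier scavenger lipocalin 2, rose 1.45-fold, a lower bound at best from a control mean of 5.63; the other 11 did not pass and 5 values were below 0. Adjusted over the list alone, 3 were higher, and camera's adjusted p was 0.0231 (0.734 with an estimated correlation as an adjusted p). By ranks camera's adjusted p was 0.139. It was 0.249 without the arrays with the most Gh and 0.126 and 0.0625 without control replicates 3 and 2 in turn. Over the list alone 5 passed without control replicate 4 and 5 without transgenic replicate 2. Lymphocyte and mast cell markers were lower as a list (camera adjusted p = 0.0162; adjusted p = 0.557 with an estimated correlation), although only Ighm, the immunoglobulin heavy chain, passed among 16, also over the list alone, where 2 passed without control replicate 1 and 2 without transgenic replicate 1. Ighm fell 2.37-fold (9.62 ± 0.05 to 8.38 ± 0.18). Other Ighm probe sets read -1.15 (limma adjusted p = 2.43e-04 over probe sets) and -0.97 (adjusted p = 0.00962). A further one read -0.275 (adjusted p = 0.146), and the rest read from -0.13 to 0.09 without passing. Without the arrays with the most 18S signal, camera's adjusted p for the lymphocyte list was 0.0754. It was 0.0561 after renewed quantile normalization, 0.066 with the mean of probe sets and 0.0513 with the unequal-variance test.

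**Figure D3:**
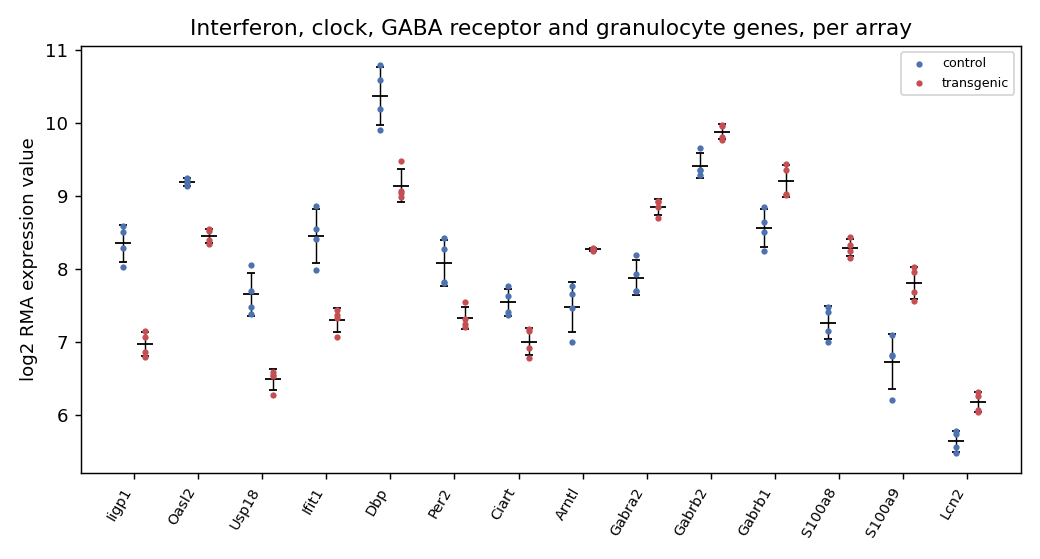
Log2 RMA expression values per array of interferon response genes (Iigp1, Oasl2, Usp18, Ifit1), clock genes (Dbp, Per2, Ciart, Arntl), GABA receptor subunits and granulocyte genes; points are arrays (blue control, red transgenic), dashes are means and bars are SDs of n = 4. Dbp fell from a mean of 10.37 to 9.14 while Arntl rose from 7.47 to 8.27.

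Lists of tissue neighbouring the ganglion also differed. Central nervous system markers were higher by a median of 0.40 (camera adjusted p = 3.83e-04; adjusted p = 0.734 with an estimated correlation). Aqp4, the water channel of astrocytes, rose 1.69-fold and was the only 1 of 17 to pass, while 4 were higher over the list alone, with Cbln1 at 0.70 and Zic1 at 1.01. Over all genes 0 passed without control replicate 1, transgenic replicate 3 or transgenic replicate 4, and 2 without control replicate 2 or 3. Over the list alone 1 passed without control replicate 1, 2 without control replicate 4 or transgenic replicate 3, 8 without control replicate 3 and 9 without transgenic replicate 1. Gfap read 8.63 and 8.29 on control replicates 1 and 4, 10.20 and 10.22 on control replicates 2 and 3, and 10.77 to 11.24 on transgenic arrays. Skeletal muscle markers were lower as a list, with a median of -0.51 (camera adjusted p = 0.00356; adjusted p = 0.734 with an estimated correlation), but 0 of 17 passed limma over all genes or over the list alone, 10 had an unadjusted p under 0.05, and 0 passed the unequal-variance test. Over the list alone 11 passed without control replicate 2 (1 higher, 10 lower) and 10 without control replicate 4, all lower. The muscle actin Acta1 read 9.20 and 9.40 on control replicates 1 and 3 and 6.60 to 7.07 on the others, and without those 2 arrays camera's adjusted p was 0.328.

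Ion channel and energy lists shifted slightly. Voltage-gated potassium and HCN channels had a median of 0.11 (camera adjusted p = 0.0324; adjusted p = 0.734 with an estimated correlation) with 0 of 23 passing limma, also over the list alone, 6 at an unadjusted p under 0.05 and 0 by the unequal-variance test. Calcium channels and calcium handling genes had a median of 0.13 (camera adjusted p = 0.0426; adjusted p = 0.770 with an estimated correlation), and the calcium-binding protein calretinin (Calb2) rose 1.39-fold as 1 of 25, with 3 higher over the list alone. Oxidative phosphorylation genes had a median of 0.05 (camera adjusted p = 0.0426; adjusted p = 0.734 with an estimated correlation), with only Ndufa12 past the test among 80, also over the list alone. Ndufa12 was higher by 0.64 at that probe set, while the next brightest read -0.28 (adjusted p = 0.0933 over probe sets) and another -0.06. After renewed quantile normalization camera's adjusted p was 0.110, 0.141 and 0.228 for these lists. Without the arrays with the most 18S signal the median was 0.03 for calcium channels (adjusted p = 0.728) and 0.07 for potassium channels (adjusted p = 0.255). The Kv4 channel gene Kcnd2, like Gfap, was lowest on control replicate 4 (7.57) and highest on transgenic replicate 3 (9.44). By ranks camera's adjusted p was 0.0725 for calcium channels. For calcium channels it was 0.0574, 0.0625 and 0.371 without control replicates 1, 2 and 4 in turn, and 0.0702, 0.0611 and 0.152 without transgenic replicates 1, 2 and 3. For potassium channels it was 0.0551 and 0.0900 without control replicates 1 and 4, and 0.1 and 0.0664 without transgenic replicates 2 and 3. For oxidative phosphorylation it was 0.0574 and 0.209 without control replicates 1 and 3, and 0.149 and 0.0664 without transgenic replicates 1 and 3. Over the list alone 3 potassium channels passed without control replicate 3. Of calcium genes 1 passed over the list alone without transgenic replicate 1, 2 or 3, and 1 higher and 1 lower without control replicate 4. Over all genes 2 passed without transgenic replicate 4. Leaving out the arrays with female, 18S, Gh or Acta1 signal left 0 calcium genes past the test over all genes in each case.

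Known or proposed DREAM targets and pain genes did not pass at the probe set that represents each gene. None of Pdyn, Bdnf, Penk, Fos, Tac1, Trpv1, Trpa1, Scn10a, Ptgs2 and Ptgds passed the limma test. Pdyn (control mean 5.47) and Ptgs2 (control mean 4.54) lay below a log2 signal of 6 in both groups, near background. A change in these genes could therefore be missed. Fos, an immediate early gene, differed by 0.43 (adjusted p = 0.103), Penk, the precursor of enkephalins, by 0.37 (SE 0.30) and Pdyn, the precursor of dynorphins, by 0.04 (SE 0.08). Among 16 reported DREAM targets 0 passed over all genes, and Gfap and Fos were higher over the list alone. The dimmer Gfap probe set that rose by 3.15 (limma adjusted p = 6.22e-09 over probe sets) does not represent Gfap in this count. The remaining Gfap probe set read 0.65 without passing. Among 8 opioid peptides and receptors 0 passed, and the nociceptin receptor Oprl1 (0.36) was higher over the list alone. Another Oprl1 probe set rose by 0.50 (adjusted p = 0.0234 over probe sets). Among 13 genes of DREAM, its relatives and Kv4 partners 0 passed by either adjustment, with Kcnd2 at 0.76 (SE 0.25) and Kcnd1 at 0.17. Camera's adjusted p was 0.900, 0.970 and 0.694 for these lists, and at an unadjusted p under 0.05 they held 3, 2 and 1 genes.

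In 8 lists not called as a list, single members passed. They were Galr2, a galanin receptor, lower among 20 sensory neuropeptide genes; Cxcl10 and Alox5, lower among 29 prostaglandin pathway and inflammatory genes; and Sox11, higher 1.88-fold among 22 nerve injury genes. Only 1 of 6 Sox11 probe sets rose, the others reading from -0.34 to 0.11. The means of Galr2 (5.985 in control and 5.49 in transgenic ganglia) lay below a log2 signal of 6, near background. Further ones were the matrix protein periostin (Postn), higher 1.65-fold among 19 fibroblast genes, the tight junction gene Cldn5, higher 1.48-fold among 14 endothelial markers, the chaperone Hspa5, higher 1.40-fold among 18 stress genes, and Rps4l, lower 2.02-fold among 49 ribosomal protein genes. The strain list with Gabra2 is the last. Adjusted over the list alone, these lists in that order had 1 higher and 1 lower, 1 higher and 3 lower, 2 higher, 2 higher and 2 lower, 3 higher, 3 higher, and 1 lower. Camera's adjusted p was 0.633, 0.132, 0.969, 0.973, 0.160, 0.270 and 0.768.

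The other lists held no gene past the limma test over all genes. They covered sensory transduction channels, sodium channels, neurotrophic factors, sensory neuron subtypes, immediate early genes, satellite glia, myelinating Schwann cells, macrophages, smooth muscle, red blood cells, pituitary, adipose tissue and sex-linked genes. Together with the DREAM and opioid lists they are 16 lists of 222 different genes, of which 43 had an unadjusted p under 0.05 and 0 passed the unequal-variance test. Over all 34 lists, 29 of 629 different genes passed limma and 2 the unequal-variance test, which called 0 members of the clock, GABA, granulocyte, central nervous system and lymphocyte lists. In the 16 lists camera's adjusted p was above 0.05, the lowest being 0.106 for satellite glia. Adjusted over the list alone, Scn7a (-0.40) and Scn1a (0.36) of the sodium channels and Car3 (-0.94) of the adipose markers passed. The sign depends on the measure in 4 lists: the median was above 0 and the mean below it for immediate early genes (camera direction lower) and macrophage markers (camera direction higher), and the median was below 0 and the mean above it for nerve injury genes and strain-variable genes (camera direction higher in both).

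Some arrays carried signals that the labels do not account for. Xist, the RNA of the inactive X chromosome, read 10.20 on control replicate 3, 11.72 on control replicate 4 and 11.51 on transgenic replicate 4, and 6.10 to 6.49 on the other 5 arrays, although the labels give male mice. The Y-linked gene Eif2s3y read 4.46 on transgenic replicate 4 and 7.16 on control replicate 4, against 8.40 to 9.04 elsewhere. Growth hormone (Gh), a pituitary transcript, read 13.43 and 12.50 on transgenic replicates 4 and 3 and 9.04 to 11.15 elsewhere. An 18S rRNA control probe set read 11.06 and 10.00 on control replicates 4 and 1 and 8.33 to 8.66 elsewhere. By an exact permutation test none of 7 array measures (actin and Gapdh 3' minus 5' signal, 2 probe sets of 18S rRNA, Gh, prolactin and Acta1) separated the groups, with raw p from 0.114 for Acta1 to 0.886 for prolactin and adjusted p of at least 0.75. Yet the high 18S and Acta1 values lay only on control arrays, and the highest Gh values only on transgenic ones. A test of mean differences can miss such a pattern, so it does not show that these signals are balanced between the groups.

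**Figure D4:**
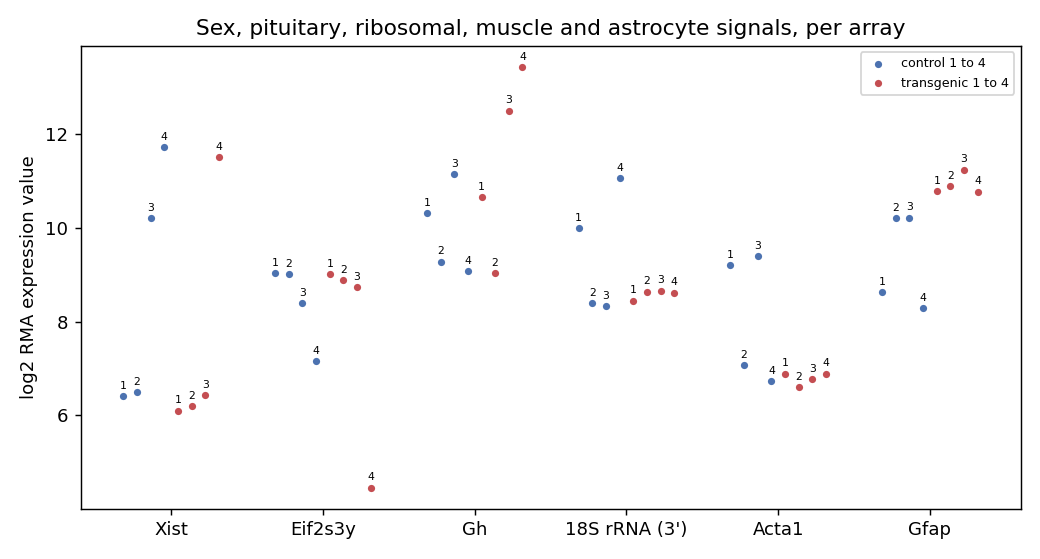
Log2 RMA expression values of Xist, Eif2s3y, Gh, an 18S rRNA control probe set, Acta1 and Gfap on each array; numbers are replicate numbers, blue is control and red transgenic. Xist reads 10.20 to 11.72 on 3 arrays and 6.10 to 6.49 on 5.

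RNA integrity was compared through the 3' minus 5' signal of actin and Gapdh control probe sets. For actin it was 0.85 ± 0.10 in control and 0.82 ± 0.05 in transgenic arrays (n = 4 each, exact permutation p = 0.771, adjusted 0.886), and for Gapdh -0.19 ± 0.15 and -0.21 ± 0.03 (exact permutation p = 0.8, adjusted 0.886).

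Among the 100 genes with the smallest p, 3 pairs were direct neighbours among measured genes: Serpina1b with Serpina1c, Ttc5 with Ccnb1ip1, and Hdhd3 with Alad. Random draws of 100 genes gave a median of 0 and a 95th percentile of 2 (permutation p = 0.0183, adjusted 0.0305 over 5 such statistics). With 50 genes there was 1 pair (permutation p = 0.129) and with 200 genes 13 (permutation p = 1e-04, the smallest that 10000 draws can give). Leaving out control replicate 4 or transgenic replicate 3 gave 2 pairs (permutation p = 0.102 each), and leaving out neighbours of 1 gene family, here Serpina1b with Serpina1c, also gave 2 (permutation p = 0.0941, adjusted 0.118), so the call is lost in each case.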

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

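The tests of female and of pituitary tissue below were chosen after the Xist values had been seen. Among 218 groups of 4 values, 16 held 1 array far from the other 3; chance flags about 1 in 20 groups.

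On transgenic replicate 2 these were Plppr1 (8.76), Galc (5.70), Rps4l (8.94), Hspa1a (8.96) and Cxcl10 (7.22). On transgenic replicate 1 they were Clasp2 (10.22), Tac1 (12.53), Kcnk2 (8.87) and Kcnj8 (6.80), and on transgenic replicate 4 Dbp (9.48) and Xist (11.51). On control arrays they were Slc4a1 (6.85) on replicate 1, Lyz2 (10.17) and Pspn (5.30) on replicate 2, and Rpgrip1 (10.89) and Trpc1 (8.79) on replicate 4. Of these genes Plppr1, Galc, Rps4l, Cxcl10, Clasp2, Dbp and Rpgrip1 passed the gene test, with all 4 arrays of a group on 1 side of the other group.

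Xist was high on 3 arrays labelled male, and female tissue in the RNA may be the source. That explanation was asked to place all 9 values of Eif2s3y, Kdm5d and Uty on these arrays below the other 5 arrays; 8 were below, so the requirement was missed by 1 value. The exception was Uty on control replicate 3, at 7.09 within the range of 6.94 to 7.43, while all 3 genes were low on control replicate 4 and on transgenic replicate 4. Since Xist is the RNA of the inactive X chromosome, pituitary tissue could be its source only if it came from a female animal. That explanation stays open too. It was first tested as a correlation of Gh with Xist, which was weak, and that test was replaced after its result was seen because Xist falls into 2 clusters; Gh on control replicate 4, the array with the most Xist, was 9.08, the lowest of the control arrays, but transgenic replicate 4 had the highest Gh. Transgenic replicate 3 had Gh at 12.50 with Xist at 6.43. The pituitary genes Prl (11.86, 8.81 and 12.50) and Cga (7.88, 7.32 and 10.11) were highest within their groups on control replicates 3 and 4 and transgenic replicate 4, the arrays with high Xist. High Xist stood beside Eif2s3y of 8.40 on control replicate 3 and 7.16 on control replicate 4, against 4.46 on transgenic replicate 4. A wrong sex label alone does not account for the Y-linked signal on these 2 control arrays; on transgenic replicate 4 it stays open. No biological explanation was tested.

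No other split of the arrays reached the gene and probe set counts, while other splits did reach the list count. The smallest share this test can give is 1 of 35 splits. Every other split mixes control and transgenic arrays, which widens the spread within its groups. The split counts are therefore no clean measure of chance. Among the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave 364 genes (highest other split 12), and 1 gave 1236 probe sets (highest other 9). For the 10 lists, 4 of the 35 splits gave as many, the highest other split giving 11. By list, 1 of the 35 splits gave a camera p as small as the real one for interferon response genes, 3 for clock genes, 5 for lymphocyte markers, 7 for granulocyte markers, 6 for potassium channels, 8 for central nervous system markers, 8 for oxidative phosphorylation genes, 13 for calcium channels, 9 for glutamate and GABA receptors and 15 for muscle markers.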

How the results depend on the processing

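Tests that leave out the arrays with female, 18S, Gh or Acta1 signal, ask for a second probe set or drop family neighbours were chosen after the results were seen. The cause of the changes below was not tested, beyond fewer arrays or probe sets where arrays or probe sets were left out. Against 364 genes and 1236 probe sets, the replicate block gave 672 genes and 2017 probe sets; deviations of same-numbered arrays correlated at 0.25, 0.01, 0.30 and 0.34, and 3 of 4 control arrays were closest to the transgenic array of their number, a hint from the data and not a pairing in the design. With the block 1 muscle marker was higher over all genes, and 1 was higher and 7 lower when adjusted over the list alone. For potassium channels 1 passed over all genes and 5 over the list alone. Oxidative phosphorylation genes had a camera adjusted p of 0.0706. Over all genes the block gave 5 central nervous system markers, 5 glutamate and GABA receptors and 3 calcium genes, all higher. It also gave 10 interferon response genes, all lower, and 1 clock gene higher and 6 lower. Over the list alone 8 central nervous system markers and 7 calcium genes were higher, and 12 interferon response genes lower. Of glutamate and GABA receptors 11 were higher and 1 lower. The probe set with the largest SD gave 697 genes, an adjusted p under 0.1 gave 703, an unadjusted p under 0.05 with at least 1.5-fold gave 240, a second probe set in the same direction 118, and the unequal-variance test 49 genes and 166 probe sets. Probe sets above the median signal gave 805. Leaving out single arrays gave 229 to 349 genes, 755 to 1271 probe sets and 7 to 11 lists; without transgenic replicates 2 and 3 in turn 755 and 783 probe sets passed. Without the arrays with female signal 213 genes passed, without 18S arrays 227 genes and 760 probe sets, without Gh arrays 98 genes and 392 probe sets, and without Acta1 arrays 171 genes and 649 probe sets; 177, 194, 97 and 158 of these genes were among the 364. Lists numbered 10 in the main test, 6 after renewed quantile normalization, 6 with the mean of probe sets, 7 by ranks, 5 with the unequal-variance test, 5 without 18S arrays and 0 with an estimated correlation. Kcnip3 turned from 0.03 to -0.0373 after renewed quantile normalization, -0.0169 with array weights and -0.085 without 18S arrays, and ran from -0.0133 to 0.0933 without single arrays. The actin 3' minus 5' difference of -0.03 ran from -0.0642 to 0.00917 and the Gapdh one of -0.01 from -0.0717 to 0.0483 without single arrays. Neighbouring pairs, 3 in the main test, numbered 1 with 50 genes, 2 without family neighbours and 2 to 5 without single arrays. Of 105 named genes under 22 settings, 2072 results kept their direction and side of the threshold, 47 gained it, 140 lost it and 24 turned. Those that turned did not pass the test: after renewed quantile normalization Trpv1 (-0.0378), Trpa1 (-0.0234) and Scn10a (-0.0533); with the mean of probe sets Ptgs2 (-0.0525); with the largest SD Scn1a (-0.04); with array weights Trpv1 (-0.0233) and Scn10a (-0.0501). Without the arrays with female signal they were Trpv1 (-0.163), Trpa1 (-0.06), Scn10a (-0.0433) and Alas2 (-0.0117), without 18S arrays Pdyn (-0.065) and Scn10a (-0.095), and without Acta1 arrays Pdyn (-0.005). Without single arrays Trpv1 ran from -0.0608 to 0.116, Trpa1 from -0.0392 to 0.111, Scn10a from -0.0483 to 0.0817, Pdyn from -0.0117 to 0.0817 and Ptgs2 from -0.035 to 0.095.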

Other observations

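The tests of clock phase and the choice of doubtful arrays to leave out were made after the results had been seen, as were the counts in fixed bins and in evenly mixed splits and the shares over clock members that had not passed. Several of the largest differences lay near each other on the chromosomes. The richest stretch of 10 Mb held 8 of the 100 genes with the smallest p, with Ap5m1 (0.71), Ttc5 (0.88) and Ccnb1ip1 (0.83) higher and Ang (-2.60), Rpgrip1, Chd8 (-0.82), Ppp1r3e (-1.05) and 1 predicted gene lower in transgenic ganglia. The direction of Chd8 is not established, since its other probe set read 0.77 (ratio -0.939). Random draws gave at most 8 (permutation p = 0.002 over 1000 draws, adjusted 0.005 over 5 statistics). Another bin held Myo7a and Acer3, both higher, with Rsf1 (0.52), and another Ahnak2, Ighm, Zfp839 (-0.51) and Zfp386 (-0.78), all lower. In all, 10 bins held 3 or more of the 100 genes, where random draws gave a median of 3 and at most 9.

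Large differences at single genes may come from chromosome regions whose origin differs between a transgenic line and its controls on a mixed C57B/6XCBA background. The test set for this gave 3 neighbouring pairs, above the 95th percentile of 2, but it also asked for more pairs than every other split of the arrays, and 1 split gave 5. That split keeps 3 of 4 arrays of each group together and so is no measure of noise; the 18 splits with 2 arrays of each group on either side gave at most 2. Chromosome regions stay open, because the planned count at 100 genes loses its call without Serpina1b with Serpina1c (permutation p = 0.0941). That pair does not account for the count at 200 genes. There 13 pairs stood against at most 10 in random draws and at most 9 in any other split. Sequence differences or transcript ends under single probe sets also stay open, since a second probe set showed a median of 0.622 of the called difference (95% interval 0.445 to 0.734, 115 genes), with 43 genes under 0.25 and 69 with the same direction at an unadjusted p under 0.05. Tissue of the other sex and ribosomal signal stay open. Leaving out those arrays left the named top differences at a median ratio of 0.998 and 0.988. But these genes were picked as the largest differences that passed the test with groups that do not overlap. That choice favours a ratio near 1, though it does not fix it. The gene count fell from 364 to 213 and 227, of which 177 and 194 were among the 364. An effect of daDREAM on these genes also stays open and was not tested apart from them. All transgenic samples share the tag tg16. If it names a single line, an effect of daDREAM cannot be told apart from other traits of that line.

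The clock genes may reflect a different clock phase at dissection. Genes on the Dbp side were lower by a mean of -0.45 and those on the Arntl side higher by 0.35, a difference of 0.805 between the groups (exact permutation p = 0.0286, the smallest possible). The test includes the genes that raised the idea, and 0.805 was at first read as support for it. Over the 8 members that had not passed, the difference was 0.36 in the same direction (exact permutation p = 0.0571). Choosing members that had not passed makes this value smaller. It therefore cannot tell phase apart from a change in the called genes alone. Leaving out the arrays with female signal left a share of 0.874 and leaving out those with 18S signal 1.114, and over the members that had not passed the shares were 1.18 and 1.36, which argues against both as the whole cause. An effect of daDREAM on clock genes stays open, untested, and times of dissection are not given in the sources used here.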
